A study of Homo sapiens with 4 samples.

How the data were processed

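Total RNA was extracted from NCI-N87 cells with Trizol and sequenced on libraries made with a standard Illumina protocol, per the labels' protocols. The labels describe 4 samples, 2 with the ZSCAN18 vector and 2 with the empty vector, transfected for 24 hours and then kept under puromycin for 4 days. The submitters' processing notes name cutadapt 1.9, FastQC 0.10.1, HISAT2 2.0.4, StringTie 1.3.4d, edgeR 3.2.5 and DESeq2, without the role of each. Per the file headers, the authors deposited 1 table with an FPKM per library and 60612 genes, together with gene positions, a linear fold change, its log2 value, a p-value, a q-value and a mark of significance. In the deposited table an FPKM of 0.0001 stands for no signal, and 30324 genes held it in all libraries. The log2 of the ratio of the summed FPKM of the 2 groups was compared with the log2 fold column of the deposited table, and 0 genes differed by more than 0.001. The authors' p-value and q-value columns come from their own model, whose details are not given in the sources used here, and they were only described.

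The empty vector columns carry the sample titles. The other 2 FPKM columns carry a name that matches no sample title, and they were assigned to the ZSCAN18 group by elimination, because the table sets them against the empty vector and the series has no other group. Which of these 2 columns belongs to which ZSCAN18 sample is not known, and the numbers 1 and 2 used here are those of the columns. The level of ZSCAN18 was looked at as a check of this assignment. The genome build is not given in the sources used here. Of the gene identifiers in the table, 58394 were found in GENCODE release 29 (GRCh38); 72.7% of these had the same start and end there, and 99.74% a start within 100 kb, so coordinates are given as GRCh38.

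FPKM are not counts, so no count model was used. Depth was estimated from the deposited FPKM of 22313 genes with a single exon and a single transcript. Their FPKM was multiplied by transcript length in kb, and the most common value within a preset window was assumed to be 1 fragment. These values gave about 23100000, 23400000, 23800000 and 24600000 fragments. The window bounds the depths that could come out, so they rest on this assumption. Only 25.3 to 26.5% of low values lay within 0.02 of a whole multiple of the assumed fragment, so fragments per gene could not be recovered. At the lowest depth the counting error of a 1 kb transcript is 20.8% of its value at an FPKM of 1 and 6.6% at an FPKM of 10. The correlation of log2 values across genes was 0.981 between the ZSCAN18 libraries, 0.980 between the empty vector libraries and 0.969 to 0.971 across the groups; genes are not independent replicates.

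Genes with an FPKM of at least 1 in at least 2 of the 4 libraries were tested, 11822 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a term for the group, and eBayes with an intensity trend moderated the variances (2 residual and 2.01 prior degrees of freedom). P-values are two-sided and were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Fold changes on log2(FPKM + 1) understate the change of genes with low FPKM. An exact permutation test of 2 against 2 libraries cannot go below a p of 0.333, so the model's values are given. Gene lists, 43 in number, were tested with camera from limma at a preset inter-gene correlation of 0.01 over the 37 lists with at least 5 tested genes, and again with an estimated correlation. In the preset form, which takes the correlation as known, 17 lists passed, 7 up and 10 down. With the estimated one 0 passed, and 7 lists had an unadjusted p under 0.05. The estimated form rests on the 2 residual degrees of freedom, so few lists could pass it. Its adjusted p therefore cannot decide whether a list changed. Several genes stand in more than 1 list, among them ME1, SLC7A11, TP53INP1, BAMBI, CDKN2B and TGFB2.

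The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes ZSCAN18, TP53INP2, MKI67, CDKN1A, MYC, CCND1, ERBB2 and CDH1 in any case. It adds the 10 largest positive and 10 largest negative fold changes among genes with a symbol, an adjusted p under 0.05, both ZSCAN18 libraries on the same side of both empty vector libraries and a mean FPKM of at least 2. From each list it takes up to 4 genes with the smallest unadjusted p. That "a symbol" leaves out names made from a clone was settled after the values were seen. It left out AL662899, with a log2 fold change of 3.21, and AL358113, with 2.76, which would otherwise have been among the 10 largest increases. Some genes that the rule names, or that belong to the lists, are not reported here. Levels of Y-linked genes and XIST were tested with the rest and are not listed.

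The gene test was checked on simulated data with 200 changed genes of 11822, in 10 runs of 2 against 2 libraries. It recovered 62.6% of genes changed by a log2 of 1 and 86.4% of those changed by 2, and 5% of its calls were false. The residual variances were shuffled among the simulated genes, which removes the trend of variance with level that the real fit uses. No smaller changes were planted, while the genes called in the real data had a median absolute log2 fold change of 0.79. These rates may therefore not hold for the real data. Camera found 50 of 50 simulated lists shifted by 0.3 and 0 of 350 unshifted lists. The simulated genes varied independently and their lists were drawn at random. The check therefore does not show how often camera falsely calls lists of genes that vary together. Enrichment of gene ontology terms given in the deposited table was added after the data were examined, as a one-sided Fisher's exact test over the tested genes that carry a term, for terms with 10 to 300 such genes. The tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

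The alternatives left out each library in turn, added the replicate number as a block, and used pseudocounts of 0.1 and 0.01. They dropped the filter on low values or raised it to an FPKM of 5, rescaled the libraries by the median of ratios or by quantile normalization, left out the variance trend, used robust variances, summed genes that share a symbol, and changed the thresholds. Lists were also tested with fry from limma. Count models planned for the case that the table held counts were not run.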

Results

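RNA sequencing was carried out on 4 libraries of NCI-N87, an established human gastric carcinoma cell line that carries an amplified ERBB2 gene. In 2 libraries the cells carried a puromycin-selectable vector expressing ZSCAN18, a zinc finger protein with a SCAN domain, and in 2 libraries they carried the empty vector. The RNA was taken after 5 days with the vector, of which 4 were spent under puromycin. The series asks how ZSCAN18 bears on the proliferation of gastric cancer cells, and its single comparison is ZSCAN18 against empty vector. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). Depths were estimated by assuming that the most common low value of FPKM times transcript length, within a preset window, is 1 fragment. They came to about 23100000 and 23400000 fragments in the ZSCAN18 libraries. In the empty vector libraries they came to 23800000 and 24600000. At the shallowest of these depths a transcript of 1 kb at an FPKM of 1 rests on about 23 fragments, and its counting error is 20.8% of the value. The number of genes at an FPKM of 1 or more was 11738 and 11700 with ZSCAN18 and 11498 and 11493 with the empty vector. The 4 libraries are not said to come from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

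ZSCAN18 itself (ENSG00000121413, chromosome 19, 58083838 to 58118427, minus strand, GRCh38 coordinates) was higher in both libraries of the ZSCAN18 group, whose columns were assigned to it by elimination and not by a label. Its FPKM was 116 and 112 in the ZSCAN18 libraries and 0.108 and 0.144 in the empty vector libraries. The log2 fold change on log2(FPKM + 1) was 6.67 (SE 0.059), and the adjusted p from limma was 4.13e-04. The added pseudocount holds this value down, because the gene lay far below an FPKM of 1 without the vector. In the authors' deposited table, which uses the plain ratio, the log2 fold change was 9.82. Without the first or the second ZSCAN18 library the fold change stayed at 6.65 or 6.70, while the adjusted p was 0.0864 or 0.0849.

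Across the transcriptome, 209 of 11822 tested genes changed at an adjusted p under 0.05 in limma, of which 94 were higher and 115 lower with ZSCAN18. The median absolute log2 fold change of these genes was 0.79, and 64 of them reached 1 or more, 32 in each direction. An unadjusted p under 0.05 in limma was given to 3174 of the tested genes. With 2 libraries per group, a gene that did not pass cannot be taken as unchanged. All 209 had both ZSCAN18 libraries on the same side of both empty vector libraries, a separation that 60.2% of all tested genes also showed and that chance gives to 33.3%. The calls need all 4 libraries: 0 genes passed without either ZSCAN18 library, with 2106 and 2338 at an unadjusted p under 0.05 in limma, and 1 gene, ZSCAN18, passed without either empty vector library. In each of those 4 fits all 209 genes kept their direction, which could not change because the groups did not overlap in these genes. Rescaling the libraries by the median of ratios gave 93 higher and 187 lower genes, beside 94 and 115 as deposited.

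**Figure D1:**
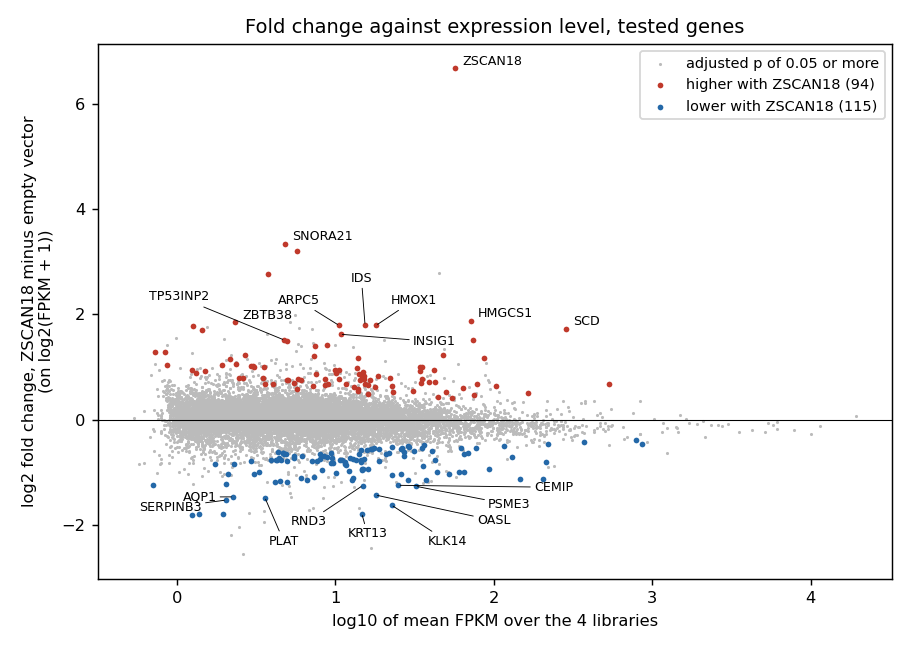
The log2 fold change of each tested gene on log2(FPKM + 1), ZSCAN18 minus empty vector, is plotted against the log10 of its mean FPKM over the 4 libraries, with Y-linked genes and XIST left out. Red points are the 94 genes higher and blue points the 115 genes lower with ZSCAN18 at an adjusted p under 0.05; ZSCAN18 stands apart at 6.67, and the other labelled genes lie between -1.79 and 3.34.

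Beyond ZSCAN18, the largest increases included 3 genes of the sterol and fatty acid synthesis lists. HMGCS1, an enzyme of the mevalonate pathway, rose from an FPKM of 30.2 ± 2.87 (SD, n = 2) to 113 ± 2.47. SCD, the desaturase that makes monounsaturated fatty acids, rose from 131 ± 0.831 to 436 ± 14.1, and INSIG1, which restrains sterol regulatory proteins in the endoplasmic reticulum, rose from 4.79 ± 0.602 to 16.8 ± 1.12. HMOX1, which breaks down heme, rose by a log2 of 1.79 (SE 0.081), as did ARPC5, a subunit of the actin-nucleating Arp2/3 complex (SE 0.109). IDS, a lysosomal sulfatase, rose by 1.80 (SE 0.067), and ZBTB38, a zinc finger protein that binds methylated DNA, by 1.85 (SE 0.083). The adjusted p of these 7 genes in limma lay between 0.0159 and 0.0307. SNORA21, a small nucleolar RNA, was listed at 9.61 ± 1.72 against 0.0408 ± 0.0089; it lies inside RPL23 on the same strand, so its reads cannot be separated from those of its host with certainty. TP53INP2, a protein that takes part in autophagy, rose from 2.0 ± 0.337 to 7.55 ± 0.722 (log2 1.51, SE 0.121, adjusted p = 0.0357).

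The largest decreases included secreted, membrane and keratin genes. KRT13, a keratin of stratified epithelia, fell from an FPKM of 23.3 ± 0.537 to 6.06 ± 0.279 (log2 -1.79, SE 0.062), and KLK14, a kallikrein-family serine protease, fell from 34.7 ± 1.19 to 10.6 ± 0.0977 (log2 -1.62, SE 0.055). SERPINB3, a protease inhibitor of squamous epithelia, had a log2 fold change of -1.53 (SE 0.109) and PLAT, the tissue plasminogen activator, one of -1.48 (SE 0.077). The water channel AQP1 stood at -1.46 (SE 0.147) and the interferon-induced OASL at -1.43 (SE 0.054). PSME3, a proteasome activator, stood at -1.26, RND3 at -1.25, and CEMIP, which takes part in hyaluronan breakdown, at -1.25. The adjusted p of these 9 genes in limma lay between 0.0180 and 0.0409. Whether the authors' counting used strand is not given in the sources used here, and TP53INP2, PSME3, CEMIP and SQSTM1 each overlap an expressed gene on the opposite strand. IDS overlaps a clone-named gene on its own strand.

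Part of the sterol synthesis genes rose. Of 23 tested genes of cholesterol synthesis and uptake, 22 had a positive fold change, 12 rose and 0 fell over all genes tested, and 20 rose and 1 fell when adjusted over the list alone. MSMO1, which acts late in the pathway, rose from an FPKM of 38.1 ± 0.316 to 110 ± 1.38, and IDI1, an isomerase of isoprenoid synthesis, from 22.4 ± 0.188 to 45.8 ± 1.41. The list's median log2 fold change was 0.75, with a camera adjusted p of 3.77e-12 at a preset correlation and an adjusted p of 0.249 with an estimated correlation. For this and the other lists the estimated form rests on 2 residual degrees of freedom, so few lists could pass it. In fatty acid synthesis, 7 of 13 genes rose and 0 fell over all genes tested (7 and 1 adjusted over the list alone), with a median of 0.49. ACSS2, which makes acetyl-CoA from acetate, rose by a log2 of 1.42, LPIN1, a phosphatidate phosphatase, by 1.23 and FASN, the fatty acid synthase, by 0.67. The camera adjusted p of this list was 4.1e-04, and the adjusted p with an estimated correlation was 0.290. The 11 sterol and 6 fatty acid genes that did not pass included TM7SF2 at 0.17 and SREBF1 at -0.04, both named after their values were seen.

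**Figure D2:**
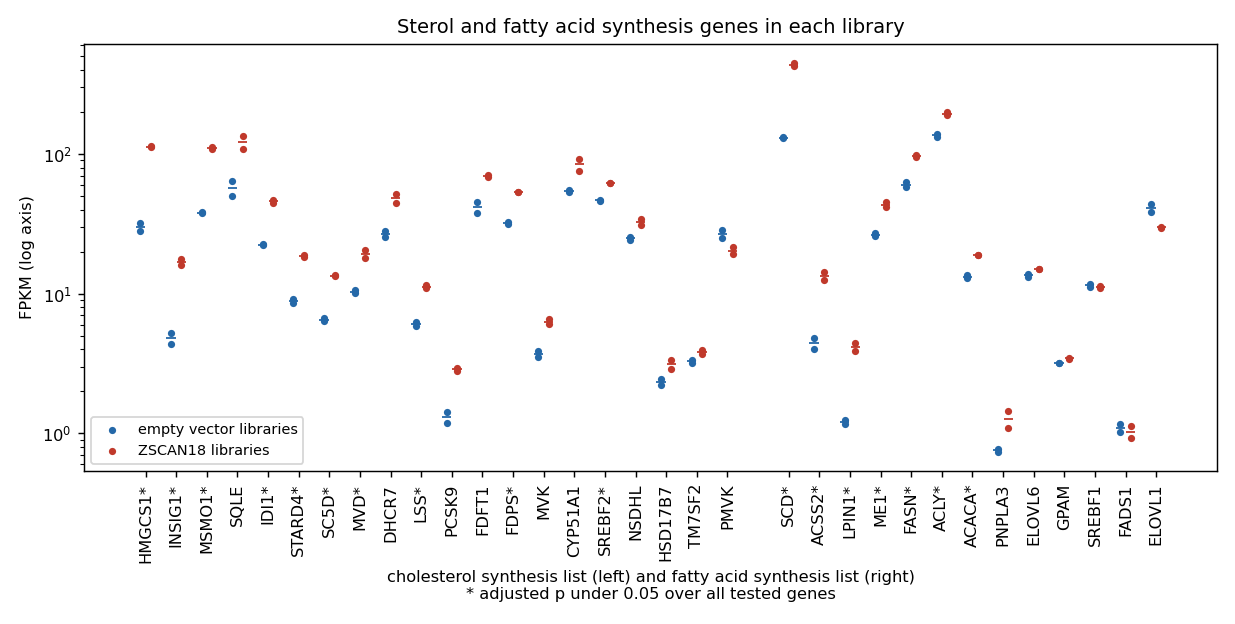
The FPKM of tested genes of the cholesterol and fatty acid synthesis lists, except 3 that are not reported here, is shown on a log axis, with a point per library, short lines at the mean of the 2 libraries of a group, blue for empty vector and red for ZSCAN18. Asterisks mark genes past an adjusted p of 0.05; HMGCS1 moved from a mean of 30.2 to 113 and SCD from 131 to 436.

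Of 18 tested genes of the NRF2 and oxidative stress list 7 rose and 0 fell over all genes tested, and 10 rose and 0 fell when adjusted over the list alone. Besides HMOX1 these included TXNRD1, the cytosolic thioredoxin reductase, at a log2 of 0.71, GCLM, a subunit of the ligase that starts glutathione synthesis, at 0.83, and SLC7A11, the cystine transporter, at 0.84. The median was 0.38, the camera adjusted p 5.35e-04 and the adjusted p with an estimated correlation 0.254. In the heat shock list of 15 genes, HSPA1A and HSPA1B rose by 1.23 and 0.94, and 7 genes rose and 1 fell when adjusted over the list alone. These 2 genes are near-identical copies, so how the reads were split between them is uncertain. The list's median was 0.23 and its camera adjusted p 0.0471, which became an adjusted p of 0.345 with an estimated correlation. That call ended without the first ZSCAN18 library (adjusted p = 0.0927), without the first empty vector library (0.0899), with the replicate number as a block (0.0797), after median-of-ratios scaling (0.0574) and in camera without the variance trend (0.0685).

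In the autophagy list, 5 of 35 tested genes rose and 0 fell over all genes tested, and 15 rose and 0 fell when adjusted over the list alone. SQSTM1, the cargo receptor p62, rose from an FPKM of 52.4 ± 0.66 to 120 ± 3.93. TP53INP1, a stress-induced relative of TP53INP2, rose by a log2 of 1.06 and MAP1LC3B, a ubiquitin-like protein of the autophagosome membrane, by 0.55; the fifth, ATG14, was at 0.59 and was named after its value was seen. The median was 0.31 and the camera adjusted p 3.31e-07, with an adjusted p of 0.249 with an estimated correlation. TP53INP2 and this list were fixed with knowledge of what the study followed up, so their direction is not independent evidence; without TP53INP2 the median was 0.30. The lysosome list did not pass (median 0.05, mean -0.001, set test pointing down, camera adjusted p = 0.994), and 1 of its 30 genes, NPC2, which carries cholesterol out of lysosomes, fell by 0.76; adjusted over the list alone 1 rose and 1 fell.

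In the lists of cell division 0 genes passed the gene test, although E2F1 and BIRC5 passed it after median-of-ratios scaling. In the list of G1/S and DNA replication, 27 of 32 genes had a negative fold change, and 0 passed over all genes tested but 8 fell when adjusted over the list alone. E2F1, a transcription factor of S-phase entry, had an FPKM of 16.7 ± 0.123 with ZSCAN18 and 21.8 ± 0.0815 with the empty vector, and the replication helicase subunits MCM7 and MCM5 had log2 fold changes of -0.33 and -0.40. The median was -0.18 and the camera adjusted p 8.6e-07, with an adjusted p of 0.249 with an estimated correlation. Of 33 genes of G2/M and mitosis, 22 were negative, 0 passed over all genes tested and 1 fell when adjusted over the list alone. BIRC5, known as survivin, had a log2 fold change of -0.58 (adjusted p = 0.0508), and CDK1, the mitotic kinase, one of -0.27. The median of that list was -0.07 (camera adjusted p = 0.00876), and the adjusted p with an estimated correlation was 0.284; in the directional fry test its adjusted p was 0.0616, and without the second ZSCAN18 library its median was -0.03. The DNA repair list of 25 genes had 22 negative members, 0 that passed, a median of -0.18 and a camera adjusted p of 9.08e-05, with an adjusted p of 0.249 with an estimated correlation. EXO1, a mismatch repair nuclease, had a log2 fold change of -0.43 and POLD1, a replicative polymerase subunit, one of -0.40.

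Of 4 genes of proliferation and the cell cycle named in advance, 0 passed the gene test. The proliferation marker MKI67 was at an FPKM of 26.1 ± 3.64 with ZSCAN18 and 32.2 ± 6.93 with the empty vector (log2 -0.28, adjusted p = 0.389). The cell cycle inhibitor CDKN1A was at 6.77 ± 0.457 and 6.74 ± 0.258 (adjusted p = 0.973) and cyclin D1 (CCND1) at 104.5 ± 1.08 and 104.1 ± 2.06 (adjusted p = 0.943). MYC was listed at 30.5 and 3.02 with ZSCAN18 and at 2.40 and 4.22 with the empty vector, so its log2 fold change of 1.42 (SE 1.073, adjusted p = 0.448) rests on 1 library. CDKN2B, an inhibitor of CDK4 and CDK6, rose from 6.9 ± 0.557 to 14.1 ± 0.975 (log2 0.94). It was the 1 gene of 13 that passed in the list of CDK inhibitors and G1 cyclins, where 1 rose and 1 fell when adjusted over the list alone (median 0.01, camera adjusted p = 0.798). In the list of p53 targets 1 of 23 genes rose, TP53INP1, 4 rose and 1 fell when adjusted over the list alone, and the list did not pass (median 0.07, camera adjusted p = 0.798). The median of the p53 targets was 0.12 without the first ZSCAN18 library and -0.003 without the second. The apoptosis list had 0 of 23 genes past the gene test, with 4 that rose when adjusted over the list alone (median 0.10, camera adjusted p = 0.373).

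Lists of respiration and translation had medians slightly below 0. Of 31 nuclear genes of oxidative phosphorylation 28 were negative and 0 passed, with a median of -0.16 and a camera adjusted p of 6.12e-06; the adjusted p with an estimated correlation was 0.249. ATP5PO, a subunit of the ATP synthase, had a log2 fold change of -0.37 and COX8A, a subunit of cytochrome c oxidase, one of -0.28. Of 39 ribosomal protein genes 35 were negative and 0 passed, with a median of -0.13 and the same camera adjusted p of 6.12e-06; the adjusted p with an estimated correlation was 0.399. RPL27 stood at -0.38 and RPL3 at 0.25, and without the first empty vector library the median was -0.06. At the preset correlation the unadjusted camera p was 9.7e-07 for oxidative phosphorylation and 9.92e-07 for the ribosomal proteins. With an estimated correlation it was 0.0306 and 0.203. Both lists had the same degrees of freedom, so these alone do not explain the difference between the 2 lists. The 13 transcripts of the mitochondrial genome had a median of -0.12 (camera adjusted p = 0.00193, adjusted p = 0.345 with an estimated correlation), with MT-ND2 at -0.20 and MT-CO3 at -0.27. Genes of the mitochondrial genome held 34.1 and 33.7% of all FPKM with ZSCAN18 and 35.2 and 34.3% with the empty vector. Quantile normalization ended the calls of the ribosomal proteins (median -0.04, adjusted p = 0.327) and the mitochondrial transcripts (median 0, adjusted p = 0.992). In the directional fry test from limma the ribosomal proteins (adjusted p = 0.144) and the mitochondrial transcripts (adjusted p = 0.0641) did not pass either, while the nuclear oxidative phosphorylation genes did (adjusted p = 0.00787). Of 26 listed replication-dependent histone genes only 8 passed the filter on low FPKM and were tested, so the list's result covers these 8 alone. All 8 had a positive fold change, and 2 rose over all genes tested and 8 when adjusted over the list alone. H2BC5 rose from an FPKM of 4.03 ± 0.2 to 10.6 ± 1.05 and H2BC12 from 25.7 ± 1 to 44.4 ± 2.24; histone genes form a family of close copies, and reads shared among them make single values uncertain. The histone median was 0.63 (camera adjusted p = 9.08e-05, adjusted p = 0.249 with an estimated correlation).

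Of 35 tested genes of the type I interferon response 27 had a negative fold change, 3 fell and 0 rose over all genes tested, and 12 fell when adjusted over the list alone. Besides OASL these were OAS2, a synthetase of the antiviral RNase L pathway, which fell from an FPKM of 12.3 ± 0.138 to 6.48 ± 0.125, and IFIT3, an antiviral protein, which fell from 19.6 ± 1.06 to 9.67 ± 1. The median was -0.24 and the camera adjusted p 1.53e-06, with an adjusted p of 0.284 with an estimated correlation. Antigen presentation genes had 0 of 14 past the gene test and a median of -0.14 (camera adjusted p = 0.0920, directional fry adjusted p = 0.00877). In the list of NF-kB targets and inflammatory cytokines 1 of 13 genes rose, NFKB2, at 0.62, and the chemokine CCL5 had a log2 fold change of -1.05 (adjusted p = 0.0540). Adjusted over the list alone 3 rose and 2 fell, and the list did not pass (median -0.10, camera adjusted p = 0.382). Its median was -0.23 without the first ZSCAN18 library and 1.8e-05 without the second empty vector library.

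In the list of WNT targets and stem cell markers 2 of 16 genes fell, BAMBI, a pseudoreceptor that dampens TGF-beta signals, by 0.65 and AXIN2, a negative feedback gene of WNT signalling, by 0.53, and 6 fell when adjusted over the list alone (median -0.27, camera adjusted p = 9.08e-05). The adjusted p with an estimated correlation was 0.249. Of 15 TGF-beta and BMP targets 3 fell and 1, CDKN2B, rose; ID1, an inhibitor of DNA binding induced by BMP, fell by 0.89 and TGFB2, a ligand of the pathway, by 0.78. Adjusted over the list alone 6 fell and 1 rose. The median was -0.31 and the camera adjusted p 0.0117, with an adjusted p of 0.290 with an estimated correlation; without the second ZSCAN18 library the median was -0.03 and the adjusted p 0.0722. In the NOTCH list 1 of 10 genes fell, the ligand JAG1, by 0.54, and HES1 had a log2 fold change of -0.47 (adjusted p = 0.0620). Adjusted over the list alone 4 fell and 1 rose. The median was -0.15 (camera adjusted p = 0.0117, adjusted p = 0.399 with an estimated correlation), and the adjusted p was 0.0793 without the second empty vector library. Among 17 YAP and TEAD targets, 2 fell, ANKRD1 by 0.66 and TGFB2, and 0 rose over all genes tested, while 7 rose and 2 fell when adjusted over the list alone (median 0.19, camera adjusted p = 0.242).

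**Figure D3:**
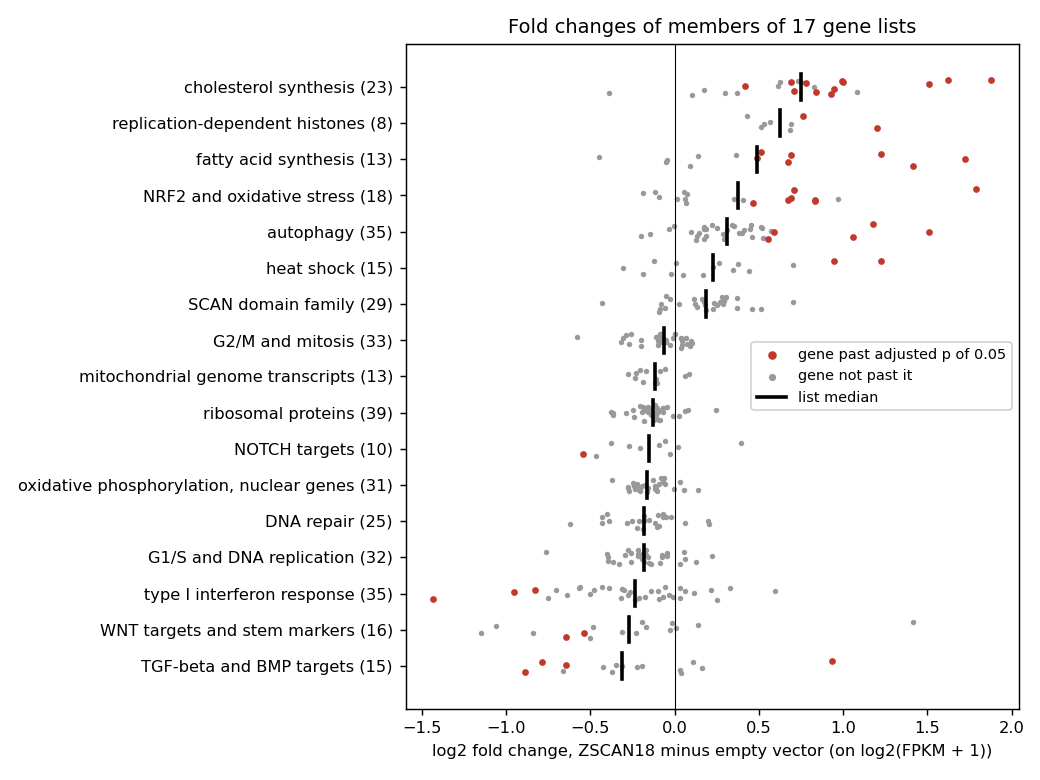
Each point is the log2 fold change of a tested gene on log2(FPKM + 1), ZSCAN18 minus empty vector, for the 17 lists past a camera adjusted p of 0.05 at a preset correlation, with red for genes past an adjusted p of 0.05 and a black bar at the list median. Medians run from -0.31 for TGF-beta and BMP targets to 0.75 for cholesterol synthesis, and the number of tested genes stands in brackets. With an estimated correlation, which rests on 2 residual degrees of freedom, 0 of the lists passed.

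CEACAM6 and CEACAM5, cell adhesion proteins of the carcinoembryonic antigen family, fell from an FPKM of 201 ± 6.58 to 91.3 ± 1.95 and from 7.27 ± 1.16 to 2.62 ± 0.107. They were the 2 of 8 genes past the gene test in the intestinal epithelium list, where 2 fell and 1 rose when adjusted over the list alone (median -0.02, camera adjusted p = 0.431, directional fry adjusted p = 0.0242), and as members of a family of close copies they may share reads. In the list of epithelial junctions and keratins KRT18 fell by 0.39 and CLDN4, a tight junction protein, rose by 0.64, of 27 genes, and adjusted over the list alone 1 fell and 1 rose (median 0.06, camera adjusted p = 0.798); quantile normalization ended the call of KRT18, at -0.21. E-cadherin (CDH1) was at 55.2 ± 13.8 with ZSCAN18 and 44.4 ± 13.3 with the empty vector (adjusted p = 0.513). S100A4, a calcium-binding protein linked to motility, fell by 1.13 and was the 1 gene of 13 past the test in the mesenchymal list, where 3 fell and 2 rose when adjusted over the list alone (median 0.05, mean -0.021, set test pointing down, camera adjusted p = 0.798). ERBB2 was at 463 ± 13.1 and 537 ± 17.4 (log2 -0.21, adjusted p = 0.103). In the list of its amplicon 1 of 13 genes fell, PPP1R1B, by 1.19, and 3 fell and 2 rose when adjusted over the list alone (median 0.13, camera adjusted p = 0.559), and 0 of 9 ERBB family genes and ligands passed, with 1 that fell when adjusted over the list alone (median -0.07, camera adjusted p = 0.542).

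The SCAN domain family, without ZSCAN18, had 22 of 29 genes positive and 0 past the gene test, with ZNF24 at 0.37 (median 0.18, camera adjusted p = 0.0263, adjusted p = 0.314 with an estimated correlation). Its adjusted p was 0.0860 without the first ZSCAN18 library, 0.0545 without the second empty vector library and 0.0675 after quantile normalization. Genes next to ZSCAN18 in 19q13.43 had 0 of 18 past the gene test and a median of 0.03 (camera adjusted p = 0.798). The hypoxia list had 1 of 15 genes higher, BHLHE40, a transcription factor of the hypoxia response, by 0.43, and 7 rose and 3 fell when adjusted over the list alone (median 0.20, camera adjusted p = 0.332, directional fry adjusted p = 0.0256). The amino acid response list had 1 of 23 higher, SLC7A11, and 1 rose and 2 fell when adjusted over the list alone (median 0.06, camera adjusted p = 0.913). Glycolysis had 0 of 20 genes past the gene test, with 1 that rose and 3 that fell when adjusted over the list alone (median -0.06, camera adjusted p = 0.175). The unfolded protein response had 0 of 21 past it, with 4 that fell when adjusted over the list alone (median -0.004, camera adjusted p = 0.332). Immediate early genes had 0 of 24 past it, with 5 that rose and 3 that fell when adjusted over the list alone (median 0.12, camera adjusted p = 0.431). Genes of DNA methylation and chromatin silencing had 0 of 20 past it, with a median of -0.01, a mean of 0.03 and a camera adjusted p of 0.908. MYC targets and ribosome biogenesis had 0 of 30 past it (median -0.04, camera adjusted p = 0.117), and median-of-ratios scaling brought this list to a median of -0.09 and an adjusted p of 0.0426. Adjusted over the list alone, 0 genes passed in the SCAN family, the 19q13.43, the DNA methylation and the MYC target lists, nor in those of antigen presentation, DNA repair, oxidative phosphorylation, ribosomal proteins and mitochondrial transcripts.

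Of 6 further lists fewer than 5 genes were tested, and they have no set test. Among 4 tested metallothionein genes MT2A, which binds zinc and copper, fell from an FPKM of 20.1 ± 1.78 to 9.98 ± 0.1. Of 27 gastric epithelium genes 4 were tested, and the highest, PSCA, reached 17.3 in a library. Markers of other cell types were listed at low levels, with 5 leukocyte markers at an FPKM of 1 or more in some library. The highest values were 1.95 for the fibroblast gene POSTN, 1.11 for the endothelial gene ESAM, 4.53 for the macrophage gene CD68 and 4.27 for ZIC2 of the HEK293 and neural-type list. CD68 was at 2.49 ± 0.318 with ZSCAN18 and 4.37 ± 0.221 with the empty vector (log2 -0.63, adjusted p = 0.0699).

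The authors' deposited table marked 512 genes as significant, 290 up and 222 down with ZSCAN18. In the authors' deposited table the mark follows an unadjusted p under 0.05 with an absolute log2 fold change of at least 1, and the largest q-value among marked genes was 0.442. A q-value under 0.05 was given to 378 genes, 158 up and 220 down, and 214 genes had both in the authors' deposited table. Of the marked genes 185 (36.1%) lay below an FPKM of 1 in all 4 libraries. Of the 209 genes called by limma, 168 (80.4%) had a q-value under 0.05 in the authors' deposited table, and those 168 had the same direction in both. They were 168 of the 329 tested genes with such a q-value in the authors' deposited table, and 84 of its 264 marked tested genes were called by limma. For MYC the authors' deposited table gave a log2 fold change of 2.34 and a q-value of 0.0449.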

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

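Leaving out genes that overlap on the same strand, camera without the variance trend and the autophagy list without TP53INP2 were tests chosen after the data were seen. The number of genes past the threshold in limma, 209 as reported, was 0 to 1 when 1 library was left out, where the lone library is assumed to vary like the other group. It was 1 with the replicate number as a block and 1 without the filter on low FPKM. The replicate numbers were not taken to pair the samples, because the numbers of the ZSCAN18 columns are tied to no sample. Deviations of same-numbered libraries had a correlation across genes of 0.034, although of 11 genes that differed over 4-fold within both groups 8 moved together by number and 3 the opposite way. The count was 370 with a filter at an FPKM of 5, 99 without the variance trend, 64 with an absolute log2 fold change of at least 1 and 1271 at an adjusted p under 0.1. It was 199 and 188 with pseudocounts of 0.1 and 0.01, 280 and 261 with median-of-ratios scaling and quantile normalization, 209 with robust variances, 201 with genes summed by symbol and 276 without overlapping genes. In each of these fits, except the sum by symbol, where it was not counted, all of the 209 genes that were tested kept their direction. Except under median-of-ratios scaling and quantile normalization it could not change, because the groups did not overlap in these genes. Where each group kept 2 libraries, their unadjusted p in limma stayed under 0.05, on the same libraries that had selected them.

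The log2 fold change of ZSCAN18 lay between 6.65 and 6.70 when 1 library was left out, with adjusted p of 0.0287 to 0.0864, and between 6.61 and 9.72 over the other alternatives, all past the threshold. The number of lists past camera was 14 to 17 in the other fits that kept 2 libraries in each group. It was 0 with an estimated correlation, which rests on 2 residual degrees of freedom, so few lists could pass. With fry, which does not compare a list with other genes, it was 17 in the directional test, where the ribosomal proteins, the mitochondrial transcripts and G2/M did not pass while antigen presentation, hypoxia and intestinal epithelium did, and 33 in either direction. The mitochondrial transcripts had a median of 0 under quantile normalization, where the set test pointed up (adjusted p = 0.992); the cause was not tested. In the authors' deposited table the 512 marked genes became 214 with a q-value under 0.05 added and 327 with an FPKM of at least 1 added. Depth limits the smallest genes: at the lowest estimated depth the counting error at an FPKM of 1 is 20.8% for a 1 kb transcript.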

Other observations

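The tests of scaling, the tests of the ribosomal and the oxidative phosphorylation list taken alone and the ontology enrichment were chosen after the results were seen, and the other tests in this part were not. Among the genes lower with ZSCAN18, the term cornification, the hardening of stratified epithelium, held 5 of 41 tested genes (one-sided Fisher's exact test, adjusted p = 0.0146): KRT4, KRT13, KRT18, KLK14 and SPRR3. KRT4, the partner keratin of KRT13, fell from an FPKM of 35.4 ± 1.61 to 16.9 ± 0.16. Cell adhesion held 8 of 134 (adjusted p = 0.0146), among them ITGB6, an integrin subunit of epithelia, at a log2 fold change of -0.58, and CEACAM6. Terms of the cell surface followed, with 4 of 22 genes for the anchored component of membrane (adjusted p = 0.0146), among them ALPP, the placental alkaline phosphatase, which fell from 51.8 ± 0.746 to 22.9 ± 0.391 and has close copies in the genome. Besides AQP1, the water channels AQP3 and AQP5 fell by 1.03 and 0.95, and the growth factor-like gene IGFL1 by 1.06. These genes outside the rule were named after their values were seen.

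Among the genes higher with ZSCAN18, the strongest terms were again of sterol synthesis. Regulation of cholesterol biosynthetic process held 8 of 23 tested genes (one-sided Fisher's exact test, adjusted p = 5.46e-09) and isoprenoid biosynthetic process 4 of 11 (adjusted p = 2.35e-04). The 9 terms that passed were all of sterol, isoprenoid or other lipid synthesis or metabolism. Autophagy, with 3 of 104 genes (0.79 expected), and cellular response to oxidative stress, with 2 of 45 (0.34 expected), did not pass. Among the lower genes, type I interferon signaling pathway, with 3 of 29, did not pass either (adjusted p = 0.162). SREBF2, which encodes the main transcription factor of sterol genes, had a log2 fold change of 0.42, while SREBF1 stood at -0.04. Both were named after their values were seen.

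The 36 sterol and fatty acid genes had a median log2 fold change of 0.688. The scaling of the libraries is argued against as the whole cause, because the median was 0.646 and 0.697 under the 2 other scalings. Gene length and GC content were taken from the longest annotated transcript of each gene, which may not be the expressed one. After a spline on length, GC content and level was removed, the median was 0.685 (bootstrap 95% interval 0.435 to 0.887). This argues against length and GC content, so measured, as the whole cause. The interval is over genes measured in the same 4 libraries and does not measure spread between cultures. Whether ZSCAN18 acts on this pathway was not tested, and the pattern was found on the same 4 libraries. Differences between the cultures in lipid supply or cell density, to which sterol genes are known to respond, stay open, since no measurement here bears on them.

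The 70 ribosomal protein and nuclear oxidative phosphorylation genes had a median of -0.137. After the same spline it was -0.055 (bootstrap 95% interval -0.098 to -0.022), and under the other scalings it was -0.089 and -0.181. For the 2 lists together neither scaling nor gene length or GC content could be decided. The 2 lists differed when taken alone, a split made after the results were seen. The intervals are over genes and do not measure spread between libraries. For the oxidative phosphorylation genes, at -0.164, scaling is argued against as the whole cause. Their median was -0.134 (interval -0.165 to -0.092) under quantile normalization, the higher of the other scalings. After the spline it was -0.104 (interval -0.124 to -0.093). This argues against length or GC content of the longest annotated transcript as the whole cause, but leaves those of the expressed transcripts open. For the ribosomal proteins, at -0.130, both stay open, since the median was -0.042 (interval -0.090 to -0.003) under quantile normalization and -0.016 (interval -0.049 to 0.011) after the spline. Whether ZSCAN18 acts on either group was not tested.

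In 51 tested genes the 2 libraries of a group differed by over 4-fold on FPKM + 1. Of these genes 76.5% overlapped another gene on the same strand, against 33% of the other tested genes (Fisher's exact test, p = 2.81e-10), which is consistent with fragments being assigned to 1 or another of the overlapping genes in different libraries. AHNAK overlaps no gene on its strand, so this explanation leaves it open; it was listed at 3.34 and 81.6 with ZSCAN18 and at 2.41 and 69.0 with the empty vector. MYC is also among the genes without such an overlap. Of the 51 genes 0 were among the 209 called by limma. A gap of that size within a group makes a call unlikely, so this does not show that called genes are free of such splitting. Of the called genes 27.8% overlapped another gene on the same strand, against 33.3% of the genes not called.

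The 4 libraries can be split into 2 and 2 in 3 ways, and 1 of them, the real one, gave as many as 209 genes, while the highest of the others gave 0. With 3 splits a share under 0.05 cannot be reached. Each of the other splits puts 1 ZSCAN18 and 1 empty vector library on either side. Any group difference then widens the spread within a side, so few calls were to be expected there.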
